A study of Ogataea angusta with 15 samples.

How the data were processed

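Gene expression of Hansenula polymorpha, a methylotrophic yeast named Ogataea angusta in the labels, was measured on 15 arrays with 2 colour channels. Per the labels, each array held RNA of treated cells in one channel and RNA of control cells of the same strain in the other. The strains were DL1-L (wild type) and its HpMET4 deletion, and the treatments sulfur starvation and cadmium. Cadmium was given as 0.6 mM in the series text and on 3 of the 4 labels of the wild type under cadmium, and on 0 of the 3 labels of the deletion under cadmium. Control cells grew in YPD and starved cells in a medium called B; the medium of the cadmium cells was not given in the sources used here.

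Per the file headers, the intensity of each spot and of its local background was read in both channels with GenePix Pro 6.0, without normalization. The flag score per spot, also per the file headers, was 0 for 170492 spots and -50 (not found) for 5098. A deposited table of 11726 lines per array holds log2 ratios of the Cy5 to the Cy3 channel, not centred, with column medians of -0.19 to 0.85. In 12 of its columns these matched the scanner files' own log ratios (99.8% to 100% within 0.01), and in 3 columns they matched in none of 5 spot orders tried (highest r 0.0133), so the table was used only for this check.

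All other values were computed from the spot intensities with R 4.3.3 and limma 3.58.1, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Background was corrected by normexp with an offset of 50, and each array was normalized by global loess (span 0.3, 4 iterations). Ratios were turned to treated over control, and the 2 spots of a probe were averaged. A probe was kept where its signal exceeded the background mean by 2 background SDs in either channel on at least 3 arrays, which left 5830 of 5837. Saturation means at least 50% of a spot's pixels. Signal over background served as the measure of depth. The unpaired array of the deletion under cadmium had 3890 spots not found, no recorded scanner settings and the fewest probes above background (3937).

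Arrays 1 and 2 and arrays 3 and 4 of a group were taken as dye-swap pairs, and the 7 full pairs were averaged to 1 replicate each. From the single array the mean dye term of the 7 pairs was subtracted. One limma fit held all 8 replicates in 4 groups, with 4 residual and 5.17 prior degrees of freedom. It tested 7 comparisons: each treatment against control in each strain, both differences between the strains, and starvation minus cadmium in the wild type. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Ratios of the arrays of a pair correlated across probes at r = 0.79 to 0.98, and those of other arrays of a group at 0.67 to 0.83. The arrays were scanned on 6 days, 1 of which held both starved strains and 1 both strains under cadmium; for both differences the list medians within that day are given where medians are.

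Gene names were read from the probe descriptions in the files, which gave 4198 probes a symbol (3636 different symbols), mostly by similarity to baker's yeast: 2716 probes were called strongly similar, 1808 similar and 626 weakly similar. Of 387 genes with several probes, the probe with the highest mean signal speaks for the gene. Called probes of 1 gene pointed in opposite directions for 4 genes in the starved wild type, 19 in the starved deletion, 0 and 52 under cadmium, 6 and 16 in the strain differences and 1 in starvation minus cadmium. The reference table of gene names uses other identifiers and was not used.

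Before the data were examined, 26 gene lists, the tests, the filter and the rule for named genes were fixed. The lists cover sulfate uptake and reduction, cysteine, methionine and S-adenosylmethionine synthesis, organic sulfur, Met4 regulators, glutathione, thioredoxin and peroxide, metal transport, iron uptake, iron-sulfur assembly, chaperones, endoplasmic reticulum folding, proteasome, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, amino acid synthesis outside sulfur, glycolysis, citrate cycle and respiratory chain, methanol use and peroxisomes, autophagy, nitrogen sources, ergosterol, thiamine with biotin and lipoate, DNA repair, histones and DNA replication, and stress storage. They were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 26 lists of a comparison), again with an estimated correlation, and with fry. Camera passed 96 of the 182 combinations, 0 with the estimated correlation (lowest adjusted p = 0.0784), and fry 88; fry asks whether members move on balance one way, not whether they differ from other genes. Named genes are the 8 highest and 8 lowest symbols with an adjusted p under 0.05 and the same sign on every array of the group (for differences, no overlap of array values), up to 4 members with the smallest adjusted p of each list that camera passed, and the same for the first 7 lists in any case. Not every gene so named is printed. After a first look, the reading of names was corrected so that accession-like words count as no symbol, which took 1 probe out of the 8 highest of the wild type under cadmium, and 5 name clashes were taken out of the lists. The METR probe, the sulfur keyword probes and the genes of the control channels were chosen after their values were seen.

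The alternatives were other background corrections, print-tip loess (span 0.4), median centring, scale normalization, median pixels, other filters, flagged spots left out, all 15 arrays with a dye term, pair or scan-day blocks, stricter thresholds, the mean over probes of a gene, and leaving out each array or pair. Lists without weakly similar probes, scan day as a fixed term and limma's treat at 1.2-fold were added after seeing the data.

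The steps were tested on simulated data with 200 changed of 5832 probes. For starvation in the wild type, limma called 7.46%, 64.2% and 100% of probes changed 1.5-, 2- and 4-fold, and 2 of 5632 unchanged ones. For cadmium in the deletion the shares were 17.9%, 74.6% and 100%, with 18 of 5632 unchanged probes called, and 0 of 5832 for cadmium in the wild type with no change simulated. A simulated shift of 0.5 in 38 proteasome probes for starvation in the deletion gave a camera adjusted p = 1.67e-24, or 0.00752 with an estimated correlation, with 0 other lists called. How camera fares with correlated members was not tested.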

Results

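Transcript levels were compared between treated and control cells of the methylotrophic yeast Hansenula polymorpha, in the wild-type strain DL1-L and in a strain lacking HpMET4, the counterpart of the yeast activator of sulfur metabolism genes. Each of 15 arrays carried treated RNA in one dye and control RNA of the same strain in the other. The starved wild type, starved deletion and wild type under cadmium had 4 arrays each, and the deletion under cadmium 3. A dye-swap pair of arrays counted as 1 replicate, which gave n = 2 per group, and the third array of the deletion under cadmium stood alone as a replicate. Of 5837 probes on the arrays 5830 were tested. Per array 5358 to 5831 lay above background, except for 3937 on that single array. Changes are log2 ratios of treated to control (n = 2 replicates per group) ± an SE pooled over all 4 groups. A probe is said to rise or fall at a limma adjusted p under 0.05. For gene lists, a second pair of counts is adjusted over the list alone, and where none is given it equals the first. An adjusted p in brackets after "or" is that of camera with an estimated correlation. Nothing in the labels says that the cultures were separate, so p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision.

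The targeted gene was looked for first. The files named 0 probes MET4, and 1 probe, KH-2783, was named for METR, the positive sulfur regulator of the mould Emericella nidulans. It was chosen after its values were seen, and the files do not say that it is HpMET4. In the control channels its log2 level lay between 11.90 and 12.56 on the 8 wild-type arrays and between 6.90 and 8.56 on 6 of the 7 arrays labelled deletion. The single array labelled deletion under cadmium read 11.21, between the strains and nearer to the wild type. The difference, deletion minus wild type, was -3.57 ± 0.59 (limma adjusted p = 0.0418), the lowest of 5830 probes, and -4.35 without the single array (adjusted p = 0.000256). The remaining deletion pair under cadmium gave treated levels of 9.39 and 10.32, with log2 ratios of 1.65 and 1.76. Every value of the deletion under cadmium below includes the array labelled in this way.

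The first question was which genes respond when sulfur is withheld from the wild type. The strongest rises included genes of sulfur and nitrogen supply. SUL1, a high-affinity sulfate permease, rose by 4.80 ± 0.35 (limma adjusted p = 7.39e-05), and YLL057C, a sulfonate dioxygenase, by 5.52 ± 0.71 (adjusted p = 0.00131). MEP2, an ammonium permease, rose 63.9-fold (adjusted p = 4.06e-06), and INO1, the inositol phosphate synthase, 71.7-fold (6.16 ± 0.89, adjusted p = 0.00244). GPH1, glycogen phosphorylase (4.28 ± 0.23), YBL064C, a peroxiredoxin (4.04 ± 0.25), and YHR209W, a methyltransferase (3.86 ± 0.21), were also among the 8 highest. The 8 lowest were CAR1, which encodes arginase (-2.75 ± 0.30), ECM13 (-2.72 ± 0.43), the pyruvate decarboxylase PDC6 (-2.59 ± 0.32), the acetate permease ADY2 (-2.58 ± 0.53), the regulator ADR1 (-2.16 ± 0.21), the drug pump PDR5 (-2.04 ± 0.39), the alcohol dehydrogenase ADH6 (-1.93 ± 0.21) and YCR061W (-1.88 ± 0.25). The probe with the highest mean signal speaks for a gene. The second probe of GPH1 also rose. Second probes read 1.78 for YBL064C, 0.44 for CAR1, 0.13 for PDR5 and 0.77 for ADH6, and those for YLL057C read 3.36 to 6.12. Treated spots of YBL064C were saturated on 3 arrays and those of INO1 on 1 array. Their changes here and in later comparisons with this group are thus lower bounds in size.

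Of the 10 probes for sulfate uptake and reduction, 5 rose, 0 fell and 5 did not pass, with 7 rising when adjusted over the list alone. Besides SUL1 these were MET3, ATP sulfurylase (2.28 ± 0.19, adjusted p = 0.000163), the sulfite reductase subunits MET10 (2.40 ± 0.16) and ECM17 (2.22 ± 0.25), and MET1, a siroheme synthesis enzyme named here after its value was seen (0.89 ± 0.19, adjusted p = 0.0166). The list median was 0.91 (camera adjusted p = 8.5e-05, or 0.108). Of 14 probes for organic sulfur uptake and use, 8 rose and 0 fell over all probes and again 8 when adjusted over the list alone (camera adjusted p = 9.39e-06, or 0.206). They included the transporters YIL166C (3.58 ± 0.44; second probe 0.03), SEO1 (1.65 ± 0.24; second probe 4.50) and AGP3 (1.01 ± 0.26). Among 16 probes for cysteine, methionine and S-adenosylmethionine synthesis, 4 rose, including the synthetase SAM2 (2.83-fold), and 2 fell, with camera at an adjusted p = 0.574. MET2, homoserine acetyltransferase, rose by 0.70 ± 0.16 (second probe 1.93), and MHT1, a homocysteine methyltransferase, fell by 0.61 ± 0.15, and both calls ended without array 2 of the starved wild type (0.51 and -0.48, adjusted p = 0.0509 and 0.0549). Of 9 probes for regulators of Met4, the cofactors MET32 (1.90 ± 0.18) and MET28 (1.92 ± 0.19) and the F-box protein MET30 (1.77 ± 0.26) rose, and 1 fell (camera adjusted p = 0.146).

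The nitrogen source list also moved upwards in the starved wild type by camera. Of 57 such probes, 20 rose and 5 fell, and 25 rose and 6 fell adjusted over the list alone (median 0.44, camera adjusted p = 7.04e-05, or 0.206). Examples were the allantoin permease DAL4 (3.37 ± 0.19; other probes -0.84 to -0.07) and the amine oxidase AMO (3.70 ± 0.31). In amino acid synthesis outside sulfur, 12 of 64 rose and 4 fell (16 and 6 adjusted over the list alone), among them LEU1 (3.27 ± 0.24), ARG1 (2.43 ± 0.20) and ARO9 (2.10 ± 0.18). That list gave a camera adjusted p = 0.0382 (adjusted p = 0.769 with an estimated correlation). That call ended without the single array (adjusted p = 0.0727) or array 1 (0.303) or 3 (0.0702) of the starved wild type. Without the second pair of this group the list turned (adjusted p = 0.903), and its medians were 0.10 and -0.24 on arrays 1 and 2. Of 31 probes for autophagy and vacuolar proteolysis 12 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000143, or 0.108). The vacuolar protease PRB1 rose by 2.81 ± 0.20, PDD7, a factor in peroxisome degradation, by 2.76 ± 0.18 and the peptidase CPS1 by 1.89 ± 0.19. In histones and DNA replication 12 of 44 rose and 0 fell, including MCM3 (1.07 ± 0.15) and MCM2 (1.06 ± 0.15), with 19 rising and 1 falling adjusted over the list alone (camera adjusted p = 8.5e-05, or 0.113). In trehalose, glycogen and general stress, called stress storage from here, 6 of 22 rose and 0 fell (6 and 0 adjusted over the list alone). In DNA repair 6 of 52 rose and 1 fell (7 and 1), RAD5 by 2.60 ± 0.39. Camera gave these lists adjusted p = 0.0165 and 0.0382 (adjusted p = 0.206 and 0.196 with an estimated correlation), and without array 1 of the starved wild type both calls ended (0.0508 and 0.0979), that of DNA repair also without array 4 (0.0526).

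Chaperone and translation lists went the other way. Of 32 chaperone probes 11 fell and 1 rose (15 and 1 adjusted over the list alone), with HSP60 at -1.62 ± 0.15, HSC82 at -1.67 ± 0.24 and SSC1 at -1.15 ± 0.17 (camera adjusted p = 7.96e-06, or 0.108). The member HSP12, a small stress protein, rose by 3.36 ± 0.32. Of 62 mitochondrial ribosomal proteins 13 fell and 1 rose (24 and 1 adjusted over the list alone, camera adjusted p = 7.95e-09, or 0.145). Of 104 ribosome biogenesis probes 20 fell and 0 rose (23 and 0 adjusted over the list alone, camera adjusted p = 4.58e-08, or 0.501), such as DBP5 (-1.17 ± 0.17) and NOP7 (-1.08 ± 0.16). Of 76 cytosolic ribosomal proteins 7 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.32, or -0.83 with median centring (camera adjusted p = 3.94e-07, or 0.592). In the citrate cycle and respiratory chain 6 of 66 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0261, or 0.501), with NDE1, an NADH dehydrogenase, at -1.49 ± 0.26. Without array 1 of the starved wild type that list's adjusted p was 0.0508. Lists that camera did not call were glutathione (median 0.18, 0 members passing), thioredoxin (0.05), metal transport (-0.02), iron uptake (-0.03), iron-sulfur assembly (0.03), endoplasmic reticulum folding (-0.16), proteasome (-0.07), glycolysis (-0.16), methanol use (0.02), ergosterol (-0.13) and thiamine (-0.05).

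In all, limma called 750 of 5830 probes in the starved wild type, 457 higher and 293 lower. The split was 483 and 543 with median centring, and the count 1512 with scale normalization and 1275 with this group alone in the fit. The count was 1339 without the single array, and equally without the full pair of its group, since either leaves that group no spread of its own. It was 244 or 193 without one or the other pair of the starved wild type and 460 or 459 without a pair of the wild type under cadmium. Starved cells grew in a medium named B and control cells in YPD, so withheld sulfur and the change of medium cannot be told apart.

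**Figure D1:**
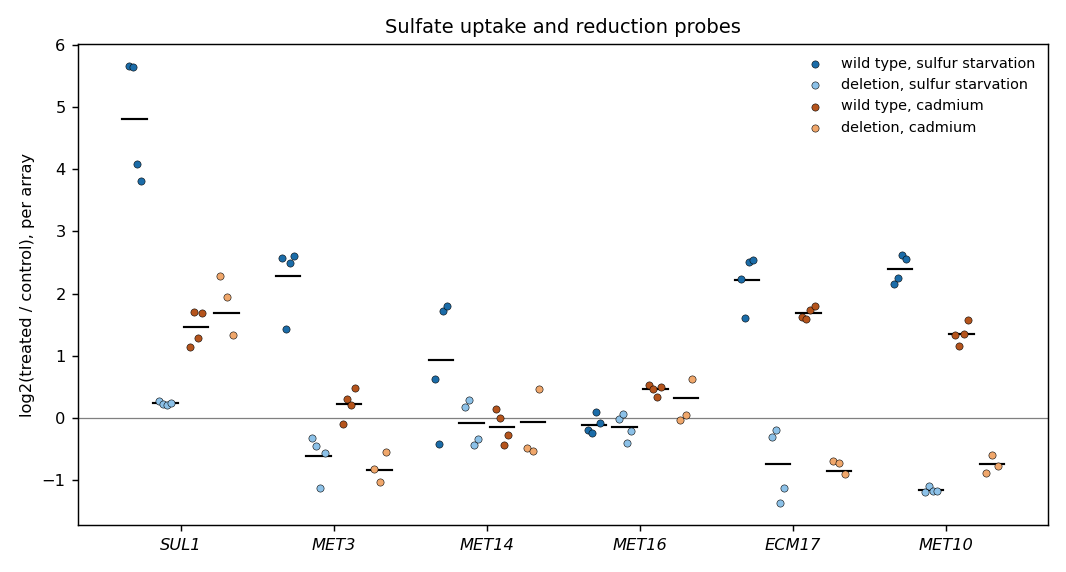
Points show the log2 ratio of treated to control per array for 6 probes of sulfate uptake and reduction in the 4 groups, and black lines the fitted group means. The starved wild type lies highest for SUL1, MET3, ECM17 and MET10, with fitted means of 4.80, 2.28, 2.22 and 2.40.

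The second question was how the strain lacking HpMET4 responds to the same change of medium. The 4 highest genes were YLL057C (5.21 ± 0.71; other probes 1.08 to 2.73), KEL1 (5.14 ± 0.32), PRB1 (4.65 ± 0.20) and HSP12 (4.57 ± 0.32). Also among the 8 highest were the ubiquitin ligase adaptor BUL1 (3.93 ± 0.20; other probes -0.30 to 3.52), RAD5 (3.82 ± 0.39) and the copper chaperone ATX1 (3.65 ± 0.20). All 8 lowest were cytosolic ribosomal proteins: RPS7B (-3.42 ± 0.16, limma adjusted p = 7.11e-06), RPS12 (-3.37 ± 0.24), RPS22A (-3.16 ± 0.19; second probe -1.08), RPL6A (-3.06 ± 0.15), RPS9B (-3.01 ± 0.20), RPL9B (-2.90 ± 0.20; second probe 0.45), RPL22A (-2.73 ± 0.23) and RPS20 (-2.73 ± 0.18). Of the 76 cytosolic ribosomal proteins 73 fell and 1 rose (74 and 1 adjusted over the list alone), with a median of -2.22 (camera adjusted p = 1.24e-41, or 0.17).

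In sulfate uptake and reduction 0 of 10 rose and 4 fell over all probes, and 1 rose and 4 fell adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.299, or 0.486). SUL1 stood at 0.24 ± 0.35 (adjusted p = 0.672), MET10 fell by 1.15 ± 0.16 (adjusted p = 0.000708) and MET22, a phosphatase of the pathway, by 0.73 ± 0.16. MET3 stood at -0.61 ± 0.19 (adjusted p = 0.0387) and ECM17 at -0.74 ± 0.25 (adjusted p = 0.0472), and both calls ended without array 1 or 4 of the starved wild type or array 2 of the starved deletion, that of MET3 also without array 3 (adjusted p = 0.0509 to 0.134). Among cysteine, methionine and S-adenosylmethionine genes 5 of 16 rose and 7 fell (camera adjusted p = 0.519). SAM2 fell by 1.69 ± 0.20, the methionine synthase MET6 by 1.21 ± 0.19 and the reductase MET13 by 1.03 ± 0.15, and MET2 rose by 2.06 ± 0.16 (second probe 0.17). Of 9 regulators of Met4, 2 rose, including MET28 (1.38 ± 0.19), and 0 fell (camera adjusted p = 0.243). In organic sulfur use 3 of 14 rose and 0 fell, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.0363, or 0.486).

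Lists with more members rising than falling came next. In the glutathione list 9 of 16 rose and 1 fell, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00163, or 0.114). GSH1, which makes gamma-glutamylcysteine, rose by 1.27 ± 0.20, the peroxidase HYR1 by 1.19 ± 0.17 and the transferase ECM4 by 1.47 ± 0.22. In the thioredoxin and peroxide list 9 of 19 rose and 2 fell (10 and 2 adjusted over the list alone) (camera adjusted p = 0.0206, or 0.17). Catalase CAT stood at 3.15 ± 0.28, superoxide dismutase SOD2 at 2.31 ± 0.27, TRX1 at 1.44 ± 0.18 and TRR1 at 1.43 ± 0.18. That list's call ended with print-tip loess and with median centring. Of 42 proteasome and ubiquitin probes 29 rose and 0 fell (31 and 0 adjusted over the list alone), led by the transcription factor RPN4 (2.84 ± 0.18), with the segregase CDC48 at 1.74 ± 0.16 (camera adjusted p = 1.19e-10, or 0.249). Amino acid synthesis outside sulfur had 40 of 64 rising and 4 falling (43 and 4 adjusted over the list alone), including ARG1 (3.00 ± 0.20), THR4 (2.07 ± 0.18) and ARG8 (1.72 ± 0.16, camera adjusted p = 4.77e-12, or 0.249). In autophagy 16 of 31 rose and 1 fell, again 16 and 1 adjusted over the list alone, with the protease PRC1 at 2.93 ± 0.22 and PDD7 at 3.01 ± 0.18 (camera adjusted p = 1.52e-06, or 0.111).

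Stress storage genes rose in 12 of 22 cases with 0 falling (13 and 1 adjusted over the list alone), among them GPH1 (2.63 ± 0.23), TFS1 (2.32 ± 0.16) and DDR48 (1.68 ± 0.16, camera adjusted p = 0.000348, or 0.114). In methanol use and peroxisomes 9 of 26 rose and 0 fell (9 and 0 adjusted over the list alone), with the beta-oxidation genes POX1 (1.70 ± 0.23) and POT1 (1.35 ± 0.25, camera adjusted p = 0.00134, or 0.249). In nitrogen source use 14 of 57 rose and 4 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.0363, or 0.486), with GAT1 at 1.83 ± 0.24 and CAR1 at -2.46 ± 0.30. Of 62 mitochondrial ribosomal proteins 46 fell and 2 rose (52 and 2 adjusted over the list alone, camera adjusted p = 5.17e-16, or 0.111). Of 66 citrate cycle and respiratory genes 32 fell and 1 rose (36 and 1), among them COR1 (-1.80 ± 0.16) and LSC2 (-1.74 ± 0.16, camera adjusted p = 4.1e-09, or 0.136). In histones and DNA replication 18 of 44 fell and 1 rose (23 and 3), including the histone HTA2 (-2.72 ± 0.29) and the replication clamp POL30 (-1.55 ± 0.16, camera adjusted p = 1.53e-05, or 0.111). In ribosome biogenesis 25 of 104 fell and 3 rose (23 and 3), with NOP1 at -1.20 ± 0.16 (camera adjusted p = 0.000395, or 0.509). Lists without a call were chaperones (7 of 32 rose and 10 fell, 8 and 10 adjusted over the list alone), metal transport (median 0.10), iron uptake (-0.12), iron-sulfur assembly (0.15), endoplasmic reticulum folding (-0.37), glycolysis (-0.29), ergosterol (-0.18), thiamine (-0.01) and DNA repair (0.13).

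In the starved deletion limma called 1747 probes, 924 higher and 823 lower. Without one or the other of its pairs the count was 840 or 986.

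The difference between the strains in the response to starvation, deletion minus wild type, asked which of these changes go with HpMET4. SUL1 lay 4.56 ± 0.49 log2 units lower in the deletion (limma log2 difference -4.56, adjusted p = 0.00119), and MET10 differed by -3.55 ± 0.23 (adjusted p = 0.000193), ECM17 by -2.97 ± 0.35 and MET3 by -2.89 ± 0.27. Within the 1 scan day that held both strains the same genes differed by -3.73, -3.76, -3.76 and -3.39. A difference of ratios also holds that of the control levels. For lists its median, deletion minus wild type, follows the word control, over all arrays and within the shared scan day. Of the 10 sulfate probes 4 were lower and 0 higher in the deletion, with 4 and 0 adjusted over the list alone (median -0.73, within the scan day -1.25; control 0.04 and 0.07; camera adjusted p = 6.11e-05, or 0.141). Other large negative differences were MEP2 (-5.11 ± 0.33; within the day -5.31), the histones HTA2 (-4.02 ± 0.42; -2.99) and HTB1 (-3.45 ± 0.57; -2.49), YBL064C (-3.98 ± 0.36; -3.57), YIL166C (-3.40 ± 0.62; -1.88; second probe 0.01) and SAM2 (-3.19 ± 0.28; -2.70). Positive ones were ECM13 (5.28 ± 0.61; 6.36; its control level was lower in the deletion by 2.70), BUL1 (2.99 ± 0.28; 2.53; other probes -0.56 to 2.81), YCR061W (2.86 ± 0.35; 3.00) and YNL155W (2.78 ± 0.36; 1.99). Behind them lay KEL1 (2.77 ± 0.45; 1.92; second probe 0.25), the drug pump ATR1 (2.67 ± 0.54; 3.14; other probes -0.44 to 0.26) and ARO3 (2.63 ± 0.35; 2.13). ADY2 differed by 2.79 ± 0.75 (2.44). That call ended without array 2 of the starved wild type, array 3 of the starved deletion or array 2 of the deletion under cadmium (adjusted p = 0.0507 to 0.0525).

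Within the other sulfur lists, 4 of 16 cysteine, methionine and S-adenosylmethionine probes were lower and 2 higher (6 and 4 adjusted over the list alone, camera adjusted p = 0.254), with MET6 at -1.69 ± 0.26 and MET2 at 1.36 ± 0.23. The second MET2 probe read -1.75, and the mean over both gave -0.20. In organic sulfur use 4 of 14 were lower and 0 higher, with 4 and 0 adjusted over the list alone (camera adjusted p = 0.0277, or 0.407). However, the median was -0.21 over all arrays and 0.12 within the scan day (control 0.11 and 0.18), and the call ended without the single array (adjusted p = 0.0737). Among regulators of Met4, MET32 (-1.57 ± 0.25) and MET30 (-1.85 ± 0.37) were lower in the deletion, CDC53 was 1 of 2 higher ones (without array 1 of the starved wild type 0.82, adjusted p = 0.0606), and MET28 differed by -0.53 (adjusted p = 0.257). Camera gave this list an adjusted p = 0.578.

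Several lists lay higher in the deletion by camera, though most of their members did not pass. In the thioredoxin list 5 of 19 were higher and 1 lower (7 and 1 adjusted over the list alone; median 0.83, within the day 0.65; control 0.06 and 0.03), with TRR1 at 2.12 ± 0.25 and CAT at 1.72 ± 0.40 (camera adjusted p = 0.00279, or 0.15). In the glutathione list 2 of 16 were higher, HYR1 (1.27 ± 0.24) and GLO2 (0.96 ± 0.25), and 0 lower (3 and 0 adjusted over the list alone; median 0.47, within the day 0.45; control -0.03 and 0.01; camera adjusted p = 0.0104, or 0.181). The GLO2 call ended without array 1 of the starved wild type (0.75, adjusted p = 0.149) or array 4 of the starved deletion (0.0607). In the proteasome list 19 of 42 were higher and 0 lower (31 and 0; median 0.89, within the day 0.85; control -0.10 and -0.03), with RPN4 at 2.60 ± 0.25 (camera adjusted p = 8.09e-15, or 0.181). Metal transport had 4 of 25 higher and 0 lower (5 and 0; median 0.23 in both; control -0.07 and -0.07), led by ATX1 (2.54 ± 0.29) and the zinc transporter ZRT3 (1.34 ± 0.23, camera adjusted p = 0.024, or 0.256). Amino acid synthesis outside sulfur had 24 of 64 higher and 4 lower (30 and 8; median 0.64, within the day 0.58; control 0.30 and -0.06), with THR4 at 1.82 ± 0.25 and ARG8 at 1.65 ± 0.22 (camera adjusted p = 3.94e-07, or 0.358). Autophagy had 7 of 31 higher and 0 lower (8 and 0; median 0.25, within the day 0.35; control 0.27 and -0.06; camera adjusted p = 0.00278, or 0.15), with PRB1 at 1.84 ± 0.29. Methanol use had 3 of 26 higher and 0 lower (3 and 0; median 0.35, within the day 0.34; control 0.26 and -0.19; camera adjusted p = 0.00448, or 0.256). Chaperones had 4 of 32 higher and 1 lower (8 and 3; median 0.38, within the day 0.30; control -0.21 and -0.37; camera adjusted p = 0.0174, or 0.203).

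Of the cytosolic ribosomal proteins 67 of 76 were lower in the starved deletion and 1 higher (72 and 2 adjusted over the list alone; median -1.86, within the day -1.65; control 0.36 and 0.49), with RPS9B at -2.85 ± 0.28 and RPS7B at -2.72 ± 0.23 (camera adjusted p = 3.35e-42, or 0.181). Histones and replication genes had 20 of 44 lower and 0 higher (23 and 0; median -0.77, within the day -0.84; control 0.25 and 0.43), including POL30 (-2.07 ± 0.22) and the primase PRI2 (-2.18 ± 0.27, camera adjusted p = 4.69e-11, or 0.0784). Mitochondrial ribosomal proteins had 13 of 62 lower and 0 higher (14 and 1; median -0.43, within the day -0.55; control -0.26 and -0.01; camera adjusted p = 2.65e-06, or 0.181). Citrate cycle and respiratory genes had 18 of 66 lower and 2 higher (21 and 2; median -0.46, within the day -0.25; control -0.18 and -0.03), with COX4 at -1.91 ± 0.25 and COX12 at -1.52 ± 0.24 (camera adjusted p = 2.02e-05, or 0.203). The other lists had medians, with those within the day second, of 0.63 and 0.67 (iron uptake), 0.26 and 0.10 (iron-sulfur assembly), 0.07 and 0.34 (endoplasmic reticulum folding), 0.05 and -0.28 (ribosome biogenesis), -0.35 and 0.00 (glycolysis), -0.18 and -0.24 (nitrogen), -0.27 and -0.10 (ergosterol), 0.07 and 0.29 (thiamine), -0.04 and -0.01 (DNA repair) and 0.34 and 0.46 (stress storage), none with a camera call. Limma called 701 probes, 295 higher and 406 lower, and 1172 without the single array. Without a pair the count lay at 277 or 302 (starved wild type), 267 or 431 (starved deletion) and 464 or 458 (wild type under cadmium).

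Cadmium, a metal that binds thiols, was the second treatment, and the first question was how the wild type responds to it. Of the sulfate probes 2 of 10 rose, both sulfite reductase subunits, and 0 fell: MET10 by 1.35 ± 0.16 (limma adjusted p = 0.00376) and ECM17 by 1.69 ± 0.25 (adjusted p = 0.00946). SUL1 stood at 1.46 ± 0.35 (adjusted p = 0.0622) and MET3 at 0.23 (adjusted p = 0.607). Adjusted over the list alone 3 rose (median 0.27, camera adjusted p = 0.00378, or 0.21). Among the 8 highest genes were the stress gene DDR48 (2.74 ± 0.16; other probes -0.10 to 0.02), YBL064C (2.66 ± 0.25; second probe -0.05), YNL208W (2.37 ± 0.23), the reductase GRE2 (2.11 ± 0.31), PUT1 (2.06 ± 0.19) and PUT2 (1.90 ± 0.28) of proline breakdown, and CAR1 (1.97 ± 0.30). The 8 lowest were the aldehyde dehydrogenase ALD4 (-2.86 ± 0.24; other probes -0.11 to 0.77), FCR1 (-2.45 ± 0.31), YLR177W (-2.24 ± 0.36), formate dehydrogenase FMD (-2.03 ± 0.32), YNL274C (-2.34 to -1.43 over its arrays), YAT1 (-1.95 ± 0.27), ADR1 (-1.94 ± 0.21) and the peroxidase CCP1 (-1.91 ± 0.23; second probe 0.15). Control spots of ALD4 were saturated on 2 arrays, so its fall is a lower bound.

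In iron uptake 5 of 13 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 0.00253, or 0.291), including the ferric reductase FRE2 (1.76 ± 0.28) and the heme oxygenase HMX1 (1.17 ± 0.20). The calls of FRE3 (0.72 ± 0.15) and of the iron carrier MRS4 (0.75 ± 0.16) ended without array 1 of the starved wild type, which the fit shares (adjusted p = 0.0647 and 0.0696). That of FRE3 also ended without array 1, 3 or 4 of the starved deletion or array 1 of this group (up to 0.0793), and that of MRS4 without array 4 of the starved wild type or array 2 of this group (up to 0.0698). Of 62 mitochondrial ribosomal proteins 9 rose and 0 fell, and 46 and 0 adjusted over the list alone (median 0.57, camera adjusted p = 1.74e-23, or 0.135), such as MRPL36 (1.14 ± 0.18) and MRPS16 (1.13 ± 0.19). Ribosome biogenesis had 1 of 104 rising and 0 falling (0 and 0 adjusted over the list alone) at a median of 0.27 (camera adjusted p = 3.95e-06, or 0.604). In the citrate cycle and respiratory chain 7 of 66 fell and 2 rose (20 and 9 adjusted over the list alone, camera adjusted p = 0.00253, or 0.583). The succinate dehydrogenase subunits SDH2 (-1.59 ± 0.27) and SDH4 (-1.51 ± 0.21; second probe 0.27) fell, and the assembly factor ATP10 rose 2.37-fold. In DNA repair 3 of 52 rose and 0 fell (4 and 0 adjusted over the list alone), including the ribonucleotide reductase subunit RNR2 (1.64 ± 0.18; second probe -0.11, camera adjusted p = 0.00543, or 0.21). Glycolysis had 2 of 25 falling and 0 rising (3 and 1 adjusted over the list alone, camera adjusted p = 0.0173, or 0.604).

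Smaller list calls were histones, proteasome and thiamine. Histones and DNA replication had a median of 0.18, with 0 of 44 passing over all probes or adjusted over the list alone (camera adjusted p = 0.0211, or 0.335). The proteasome had a median of 0.17, with 1 of 42 falling and 0 rising, also adjusted over the list alone (camera adjusted p = 0.0453, or 0.77). For thiamine the median was -0.17, with 0 of 14 passing and 4 falling adjusted over the list alone (camera adjusted p = 0.0323, or 0.604). The proteasome call ended without array 1 or 4 of this group (adjusted p = 0.169 and 0.0945), array 1 of the starved wild type, array 3 of the starved deletion or array 1 of the deletion under cadmium (0.0505 to 0.0591). The thiamine call ended without array 4 (0.0776) or the single array (0.0741). In metal transport 2 of 25 rose, the zinc regulator ZAP1 (1.11 ± 0.18; second probe -0.80) and the transporter ZRT2 (0.97 ± 0.21), and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.992). Of 16 glutathione probes 1 fell, the glutaredoxin GRX4 (-0.96 ± 0.20), and 0 rose, with 1 and 2 adjusted over the list alone. The GRX4 call ended without array 4 of this group (adjusted p = 0.0548), and that of ZRT2 without its array 1 or 4, array 1 of the starved wild type or array 2 of the deletion under cadmium (0.0522 to 0.0763). GSH1 stood at 0.72 ± 0.20 (adjusted p = 0.0913, camera adjusted p = 0.809). Lists without a call were cysteine, methionine and S-adenosylmethionine (median -0.08), organic sulfur (0.06), Met4 regulators (-0.04), thioredoxin (0.00), iron-sulfur assembly (-0.03), chaperones (0.04), endoplasmic reticulum folding (-0.13), cytosolic ribosomal proteins (0.05, and -0.28 with median centring), amino acid synthesis (-0.05), methanol use (-0.10), autophagy (0.04), nitrogen (-0.11), ergosterol (-0.17) and stress storage (0.01). Limma called 168 probes, 111 higher and 57 lower. The count was 446 without the single array, 6 or 5 without one or the other pair of this group, 108 or 107 without a pair of the starved wild type (110 without its array 1).

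The deletion under cadmium, labelled with no dose on its 3 arrays, had 2642 calls by limma against 168 in the wild type. These were 1525 and 1332 with scale normalization, which evens out response size between arrays by construction. With only the groups of a comparison in the fit they were 1596 and 1147. Heat shock proteins HSP12 (4.30 ± 0.32) and HSP26 (4.03 ± 0.36), DDR48 (4.21 ± 0.16, limma adjusted p = 2.42e-06), YNL155W (4.28 ± 0.25), MPM1 (3.68 ± 0.26), ECM18 (3.44 ± 0.23), the protease-like factor DDI1 (3.27 ± 0.20) and isocitrate lyase ICL1 (3.14 ± 0.24; second probe -0.05) were the 8 highest. The 8 lowest were YAL061W (-5.21 ± 0.29), the sterol enzyme ERG25 (-4.46 ± 0.48; second probe 0.67), the wall proteins SCW10 (-3.75 ± 0.23) and SCW4 (-3.53 ± 0.17), YOR093C (-3.49 ± 0.58), SKS1 (-3.34 ± 0.46), PRY2 (-3.26 ± 0.26) and the malic enzyme MAE1 (-3.24 ± 0.36). Of 76 cytosolic ribosomal proteins 70 fell and 0 rose, again 70 and 0 adjusted over the list alone, with RPS22A at -3.08 ± 0.19 (second probe -0.28) and RPL30 at -2.89 ± 0.20 (median -2.05, camera adjusted p = 1.04e-27, or 0.237).

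In the sulfate list SUL1 was the 1 of 10 that rose (1.69 ± 0.35, adjusted p = 0.00365), and 4 fell: MET22 (-0.98 ± 0.16), ECM17 (-0.85), MET3 (-0.83 ± 0.19) and MET10 (-0.74 ± 0.16, camera adjusted p = 0.275). The SUL1 call ended without the first pair of this group. In cysteine, methionine and S-adenosylmethionine synthesis 6 of 16 fell and 3 rose (7 and 3 adjusted over the list alone), with SAM2 at -2.93 ± 0.20, MET6 at -2.83 ± 0.19 and MET13 at -2.44 ± 0.15 (camera adjusted p = 0.0433, or 0.237). Among regulators of Met4 4 of 9 rose and 0 fell (5 and 0 adjusted over the list alone), MET28 by 2.58 ± 0.19 and the ubiquitin-conjugating enzyme CDC34 by 2.10 ± 0.21 (camera adjusted p = 0.0323, or 0.291). Both list calls ended without the single array (adjusted p = 0.168 and 0.142), the first also without array 2 of the starved wild type (0.0525). In organic sulfur use 1 of 14 rose and 3 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.613).

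Of 42 proteasome and ubiquitin probes 39 rose and 1 fell (40 and 2 adjusted over the list alone), with PRE7 at 2.18 ± 0.20 and CDC48 at 1.94 ± 0.16 (median 1.34, camera adjusted p = 9.52e-14, or 0.202). Chaperones rose in 17 of 32 cases and fell in 4 (19 and 4 adjusted over the list alone), including FES1 (2.38 ± 0.20) and SBA1 (1.62 to 2.19 over its arrays, camera adjusted p = 0.00269, or 0.202). Iron-sulfur assembly had 10 of 18 rising and 1 falling, with ISU1 at 2.14 ± 0.20, JAC1 at 1.87 to 2.11 over its arrays, NBP35 at 2.44 ± 0.15 (second probe -0.15) and NFU1 at 1.87 ± 0.16 (second probe -0.43, camera adjusted p = 0.00813, or 0.202). Thioredoxin genes had 9 of 19 rising and 1 falling, TRX1 by 1.95 ± 0.18 (camera adjusted p = 0.0242, or 0.202). The list call ended without the single array (adjusted p = 0.067). In glutathione 6 of 16 rose and 4 fell, with GLO1 at 1.59 ± 0.19 and FLD1, formaldehyde dehydrogenase, at 1.44 ± 0.18 (camera adjusted p = 0.275). Autophagy had 20 of 31 rising and 2 falling, including PDD7 (3.02 ± 0.18) and the lipase CVT17 (2.28 ± 0.15, camera adjusted p = 1.56e-05, or 0.155). Stress storage genes rose in 13 of 22 cases and fell in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00134, or 0.202), with TFS1 at 2.64 ± 0.16. Methanol use had 10 of 26 rising and 1 falling (camera adjusted p = 0.0105, or 0.291). That call ended without the first pair.

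Ribosome biogenesis had 59 of 104 falling and 7 rising (60 and 7 adjusted over the list alone), with the polymerase subunit RPA135 at -2.65 ± 0.19 and NOP1 at -2.21 ± 0.16 (camera adjusted p = 2.49e-07, or 0.376). Respiratory and citrate cycle genes had 40 of 66 falling and 5 rising (42 and 8), with COR1 at -2.37 ± 0.16 and CYT1 at -2.28 ± 0.15 (camera adjusted p = 5.21e-06, or 0.202). Histones and replication had 20 of 44 falling and 5 rising (23 and 5, camera adjusted p = 0.00422, or 0.202). Mitochondrial ribosomal proteins had 25 of 62 falling and 5 rising (26 and 5, camera adjusted p = 0.00305, or 0.291). The latter call ended without the first pair. Amino acid synthesis had 25 of 64 falling and 5 rising, THR1 by -2.64 ± 0.16 (camera adjusted p = 0.0119, or 0.58). That call ended without the single array (adjusted p = 0.067). Lists without a call had medians of -0.12 (metal transport), -0.27 (iron uptake), 0.06 (endoplasmic reticulum folding), -0.39 (glycolysis), -0.06 (nitrogen), -0.32 (ergosterol), -0.12 (thiamine) and 0.21 (DNA repair). Of the 2642 called probes 1335 were higher and 1307 lower. Saturated spots make the changes of YNL155W and CDC48 (treated, 1 array each) and CYT1 (control, 2 arrays) lower bounds in size. The same holds for the strain differences of YNL155W and SSB2 (control, 2 arrays).

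The difference between the strains under cadmium, deletion minus wild type, asked which responses to the metal go with HpMET4. ECM17 differed by -2.54 ± 0.35 (limma adjusted p = 0.00133; within the 1 scan day with both strains -2.31), MET10 by -2.09 ± 0.23 (-1.98), MET22 by -1.13 ± 0.23 (-0.96) and MET3 by -1.06 ± 0.27 (-1.04), whereas SUL1 differed by 0.23 (adjusted p = 0.761). The MET3 call ended without array 1 of the starved wild type (-1.02, adjusted p = 0.0559). Of the 10 sulfate probes these 4 were lower and 0 higher, also adjusted over the list alone (median -0.30, within the day -0.63; control 0.04 and -0.11; camera adjusted p = 0.0185, or 0.166). The list call ended without the first pair of the deletion. MET6 (-3.03 ± 0.26; -2.97), SAM2 (-2.62 ± 0.28; -2.63) and MET13 (-2.38 ± 0.22; -2.30) were lower in the deletion (their list: camera adjusted p = 0.131). The 8 highest differences were YNL155W (3.58 ± 0.36; 3.40), MPM1 (3.46 ± 0.36; 2.89), ICL1 (3.45 ± 0.34; 4.01; second probe 0.20) and YHR087W (3.32 ± 0.51; 3.08), with HSP26 (3.12 ± 0.51; 2.91), HSP12 (3.00 ± 0.45; 2.10), DDI1 (2.98 ± 0.29; 2.92) and WWM1 (2.90 ± 0.23; 2.70). The 8 lowest were YAL061W (-4.27 ± 0.41; -3.46), SCW4 (-3.85 ± 0.25; -3.72), ERG25 (-3.76 ± 0.67; -4.53; second probe 0.86), PRY2 (-3.64 ± 0.36; -3.79), SCW10 (-3.57 ± 0.33; -3.54), YOR338W (-3.55 ± 0.61; -4.06), YOR093C (-3.52 ± 0.82; -2.17) and PUT1 (-3.30 ± 0.27; -2.81). DDR48 differed by 1.47 ± 0.23, which turned to -1.35 with scale normalization between arrays.

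Iron uptake and iron-sulfur assembly went opposite ways. In iron uptake 6 of 13 were lower in the deletion and 0 higher, also adjusted over the list alone (median -0.94, within the day -0.96; control 0.22 and 0.65), with HMX1 at -1.47 ± 0.29 and MRS4 at -0.99 ± 0.22 (camera adjusted p = 0.000904, or 0.163). Iron-sulfur assembly had 8 of 18 higher and 0 lower (median 0.51, within the day 0.68; control 0.02 and -0.16), ISU1 by 2.30 ± 0.28 and JAC1 by 1.60 (camera adjusted p = 0.00329, or 0.163). In metal transport ZRT2 (-1.70 ± 0.30) and the manganese transporter SMF2 (-1.43 ± 0.29) were among 4 of 25 lower ones, with 0 higher (camera adjusted p = 0.375). Among regulators of Met4 3 of 9 were higher and 0 lower, MET28 by 2.19 ± 0.27 (median 0.58, within the day 0.31; control -0.36 and -0.25; camera adjusted p = 0.00986, or 0.205). The list call ended without the single array (adjusted p = 0.0611). Thioredoxin genes had 5 of 19 higher and 0 lower (median 0.55, within the day 0.38; control 0.06 and 0.05), TRX1 by 2.01 ± 0.25 (camera adjusted p = 0.00706, or 0.163). In glutathione 4 of 16 were higher and 1 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.245). In organic sulfur use 0 of 14 were higher and 3 lower (camera adjusted p = 0.64).

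Proteasome genes had 34 of 42 higher and 1 lower (39 and 1 adjusted over the list alone; median 1.24, within the day 1.01; control -0.10 and -0.11; camera adjusted p = 3.72e-13, or 0.172), with PRE7 at 1.83 ± 0.28 and RPN10 at 1.76 ± 0.23. Chaperones had 14 of 32 higher and 3 lower (16 and 3; median 0.62, within the day 0.73; control -0.21 and -0.25), FES1 at 2.29 ± 0.28 and SSB2 at -2.50 ± 0.31 (camera adjusted p = 0.00432, or 0.163). Autophagy had 15 of 31 higher and 1 lower (19 and 1; median 0.80, within the day 0.82; control 0.27 and 0.09; camera adjusted p = 4.54e-06, or 0.129), PDD7 at 2.80 ± 0.25. Methanol use had 8 of 26 higher and 0 lower (9 and 0; median 0.54, within the day 0.78; control 0.26 and -0.02), PER10 at 2.01 ± 0.27 and dihydroxyacetone kinase DAK at 1.30 ± 0.22 (camera adjusted p = 0.00102, or 0.204). Stress storage had 7 of 22 higher and 0 lower (7 and 1; median 0.60, within the day 0.54; control 0.21 and 0.06; camera adjusted p = 0.00583, or 0.163). That call ended with scale normalization. Cytosolic ribosomal proteins had 69 of 76 lower and 0 higher (70 and 0; median -2.04, within the day -2.17; control 0.36 and 0.75; camera adjusted p = 6.97e-31, or 0.186). Mitochondrial ones had 40 of 62 lower and 2 higher (47 and 2; median -0.97, within the day -1.05; control -0.26 and -0.07), MRPL35 at -1.95 ± 0.22 (camera adjusted p = 4.31e-12, or 0.163).

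Ribosome biogenesis had 56 of 104 lower and 1 higher (63 and 2 adjusted over the list alone; median -0.96, within the day -1.01; control 0.15 and 0.31), RPA135 at -2.83 ± 0.27 (camera adjusted p = 7.53e-13, or 0.255). Respiratory genes had 23 of 66 lower and 3 higher (27 and 5; median -0.62 in both; control -0.18 and 0.08; camera adjusted p = 0.000465, or 0.21). That call ended with scale normalization. Histones and replication had 19 of 44 lower and 3 higher (20 and 3; median -0.48, within the day -0.57; control 0.25 and 0.22), CDC21 at -1.87 ± 0.23 (camera adjusted p = 0.000407, or 0.163). Amino acid synthesis had 17 of 64 lower and 2 higher (median -0.31, within the day -0.16; control 0.30 and 0.30; camera adjusted p = 0.00537, or 0.591). That call ended with scan day as a fixed term on 15 arrays, a setting that changes the unit as well. Medians of the remaining lists, with those within the day second, were 0.08 and 0.20 (endoplasmic reticulum folding), -0.21 and 0.07 (glycolysis), 0.07 and 0.24 (nitrogen), -0.27 and -0.04 (ergosterol), 0.17 and 0.50 (thiamine) and 0.07 and 0.16 (DNA repair). Limma called 1697 probes, 837 higher and 860 lower, and 813 or 599 without one or the other pair of the wild type under cadmium.

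**Figure D2:**
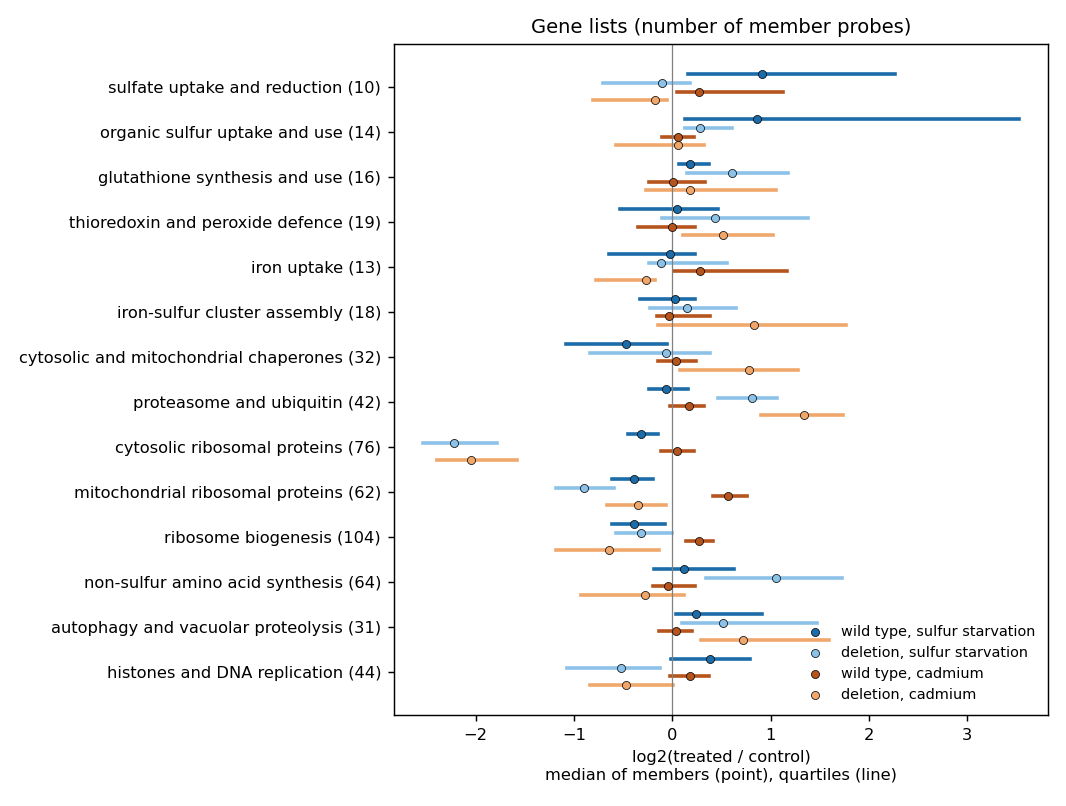
Points show the median log2 ratio of treated to control over the member probes of 14 gene lists in the 4 groups, and lines run from the lower to the upper quartile of members. Cytosolic ribosomal proteins lie at -2.22 and -2.05 in the deletion and at -0.32 and 0.05 in the wild type, where median centring gives -0.83 and -0.28.

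Within the wild type, starvation and cadmium were set against each other, although no scan day held both. MEP2 (6.58 ± 0.33, limma adjusted p = 4.02e-05), INO1 (6.29, adjusted p = 0.0232), YLL057C (5.51 ± 1.01), LEU1 (3.91 ± 0.34), AMO (3.85 ± 0.44), DAL4 (3.79 ± 0.26), YHR209W (3.73 ± 0.30) and YIL166C (3.47 ± 0.62) were highest in starvation relative to cadmium. CAR1 (-4.72 ± 0.43), PUT2 (-2.98 ± 0.40), PDC6 (-2.62 ± 0.45), the mitochondrial protein MAM33 (-2.49 ± 0.27), DDR48 (-2.48 ± 0.23), YNL208W (-2.47 ± 0.33), PUT1 (-2.34 ± 0.27) and YCR061W (-2.12 ± 0.35) were lowest. In the sulfate list 3 of 10 were higher in starvation and 0 lower, also adjusted over the list alone: SUL1 (3.34 ± 0.49), MET3 (2.05 ± 0.27) and MET10 (1.04 ± 0.23, camera adjusted p = 0.0105, or 0.187). The MET10 call ended without array 3 of the wild type under cadmium (0.97, adjusted p = 0.0535), and the list call with scale normalization. Organic sulfur use had 4 of 14 higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 4.84e-06, or 0.246). Regulators of Met4 had 3 of 9 and 0, MET32 (1.83 ± 0.25), MET28 (1.52 ± 0.27) and MET30 (1.81 ± 0.37, camera adjusted p = 0.0376, or 0.373). The last list call ended without the single array (adjusted p = 0.0573).

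Nitrogen genes had 12 of 57 higher in starvation and 4 lower (20 and 5 adjusted over the list alone, camera adjusted p = 3.08e-06, or 0.187). Autophagy had 5 of 31 higher and 0 lower (9 and 1), PDD7 at 2.54 ± 0.25 and PRB1 at 2.43 ± 0.29 (camera adjusted p = 0.00021, or 0.115). Mitochondrial ribosomal proteins had 26 of 62 lower and 0 higher (55 and 0), RSM7 at -1.59 ± 0.22 and MRPL24 at -1.62 ± 0.25 (median -1.05, camera adjusted p = 2.21e-30, or 0.0835). Ribosome biogenesis had 5 of 104 lower and 0 higher (35 and 0), NOP7 at -1.40 ± 0.22 (camera adjusted p = 1.34e-16, or 0.312). Chaperones had 5 of 32 lower and 1 higher (12 and 1), HSP60 at -1.76 ± 0.22 and SSC1 at -1.70 ± 0.25 (camera adjusted p = 8.4e-06, or 0.115). Iron uptake had 0 of 13 passing and 3 lower adjusted over the list alone (median -0.91, camera adjusted p = 0.000348, or 0.187). Cytosolic ribosomal proteins (median -0.39, adjusted p = 1.66e-06) and the proteasome (-0.22, adjusted p = 0.00926) were lower by camera with 0 members passing (adjusted p = 0.589 and 0.59 with an estimated correlation). Amino acid synthesis (7 of 64 higher and 0 lower, 10 and 2 adjusted over the list alone) had a camera adjusted p = 0.033, or 0.69 with an estimated correlation. Thiamine (3 of 14 higher, 0 lower) and histones (0 of 44 passing) both had a camera adjusted p = 0.0487, or 0.589 and 0.312 with an estimated correlation. These 3 calls ended without the single array (adjusted p = 0.0613, 0.0753 and 0.0613), array 1 (0.211, 0.137 and 0.126) or 3 of the starved wild type, or array 2 of the wild type under cadmium. The last pair of them also ended without array 1 or 4 of the starved deletion or array 4 of the wild type under cadmium. The other medians were 0.21 (cysteine, methionine and S-adenosylmethionine), 0.13 (glutathione), -0.14 (thioredoxin), 0.12 (metal transport), 0.01 (iron-sulfur assembly), -0.03 (endoplasmic reticulum folding), 0.29 (glycolysis), 0.20 (citrate cycle and respiratory chain), 0.18 (methanol use), 0.01 (ergosterol), 0.04 (DNA repair) and 0.13 (stress storage). Limma called 310 probes, 186 higher and 124 lower, split 492 and 538 with scale normalization. The count was 821 with only both groups in the fit, 577 without the single array, 124 or 91 without a pair of the starved wild type and 44 or 41 without a pair of the wild type under cadmium.

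Of the probes called in the wild type, 31 rose and 21 fell in both treatments, against 8.70 and 2.86 for independent lists, and 11 went opposite ways, against 10.05. The log2 ratios of both treatments correlated across probes at r = 0.25, with a covariance of 0.0591, though probes are not independent replicates. The labels do not say whether the treatments shared control RNA, and unchanged groups simulated with a shared control gave r = 0.50 and a covariance of 0.0229, so part of the excess may come from there. The 52 shared calls were 147 without the single array, 30 or 23 without a pair of the starved wild type and 2 or 1 without a pair of the wild type under cadmium. In the deletion 513 rose and 470 fell in both treatments, against 212 and 185 for independent lists, with r = 0.52 and a covariance of 0.366 (simulated 0.0229). Opposite ways went 141, against 396. Between the strains 234 rose and 148 fell in both under starvation, against 72.4 and 41.4, and 50 went opposite ways, against 111. Under cadmium 50 rose and 29 fell in both, against 25.4 and 12.8, and 31 went opposite ways, against 37.9. Without a pair of the wild type under cadmium its calls fall to 6 or 5, so these 79 rest on both pairs.

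**Figure D3:**
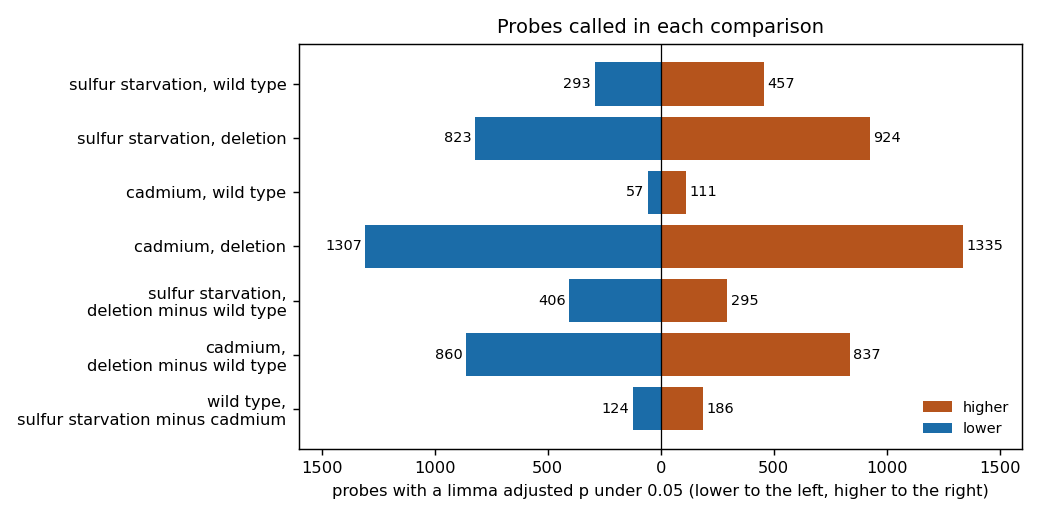
Bars show the number of probes called higher (right) and lower (left) by limma in each of the 7 comparisons. Cadmium gave 168 calls in the wild type (446 without the single array, 6 or 5 without one of its own pairs) and 2642 in the deletion. With scale normalization, which evens out response size between arrays by construction, these were 1332 and 1525. With only the groups of a comparison in the fit they were 1147 and 1596.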

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

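The splits that keep pairs whole and the tests of culture state, change of medium, a wrong label of the single array, and scan day for cadmium and for sulfate genes were chosen after the result was seen; the other tests of this part were planned.

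The response of the strains differed past the threshold in limma at 701 probes under starvation and at 1697 under cadmium. The planned splits and exchanges of single arrays break dye-swap pairs, whose arrays are not independent, and were dropped. Only 3 splits keep the pairs whole, too few for a share under 0.05. With arrays as replicates the real one, 1 in each case, called 1957 probes against 6 for the highest other under starvation, and 2740 against 1 under cadmium. Of the probes that differed at least 2-fold between strains on the other scan days under starvation, 90.8% had the same sign within the shared day.

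Under starvation the strain difference also passed camera for 14 lists, deletion minus wild type. Medians were negative for sulfate uptake (-0.73), organic sulfur (-0.21), cytosolic ribosomal proteins (-1.86), mitochondrial ones (-0.43), citrate cycle and respiration (-0.46) and histones (-0.77). They were positive for glutathione (0.47), thioredoxin (0.83), metal transport (0.23), chaperones (0.38), proteasome (0.89), amino acid synthesis (0.64), methanol use (0.35) and autophagy (0.25). Under cadmium 16 lists differed. Negative medians were those of sulfate uptake (-0.30), iron uptake (-0.94), cytosolic (-2.04) and mitochondrial (-0.97) ribosomal proteins, ribosome biogenesis (-0.96), amino acid synthesis (-0.31), citrate cycle and respiration (-0.62) and histones (-0.48). Positive ones were Met4 regulators (0.58), thioredoxin (0.55), iron-sulfur assembly (0.51), chaperones (0.62), proteasome (1.24), methanol use (0.54), autophagy (0.80) and stress storage (0.60). With an estimated correlation 0 of these list differences passed (lowest camera adjusted p = 0.0784 and 0.129). Over all 26 lists fry called 14 and 17, which need not be the lists named here.

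The first pattern weighed is that limma called 2642 probes under cadmium in the deletion and 168 in the wild type, or 1525 and 1332 with scale normalization, and 1596 and 1147 with only the groups of a comparison in the fit. Before scale normalization the median absolute log2 change was 0.49 and 0.59 in the replicates of the deletion and 0.24 and 0.19 in those of the wild type. Scale normalization evens out this size by construction, so the smaller gap there decides nothing. Without the single poor array the deletion's SD of log2 changes was 2.05 times that of the wild-type pair of the same day. This argues against that array as the cause of the larger changes, and leaves the gap in calls open. Scan day is argued against. Of 1691 probes that differed between strains on other days, 92.1% had the same sign within the shared day (r = 0.74). A wrong label of the single array stays open: 100% of 3 probes that mark the strains in the control channels lay nearer the deletion on it, too few to decide, while the METR probe lay nearer the wild type. A dose or exposure that differed between strains cannot be told apart from the deletion, because 0 of the 3 deletion arrays carry a dose in their labels, and a greater sensitivity of the deletion to cadmium may explain the pattern too.

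The second pattern is the fall of cytosolic ribosomal protein probes in the treated deletion. Normalization of bright probes is argued against as the whole cause, since the ribosomal protein median lay below that of 220 other bright probes by 1.38 or more in both treatments (smaller gap -1.38). Those probes were somewhat dimmer (mean log2 signal 13.11 against 13.42). Their own medians in the deletion were -0.23 under starvation and -0.67 under cadmium, so part of the fall may go with brightness. Scan day is argued against by strain differences of -1.65 or lower within both shared days. The control level enters these ratios, and it was higher in the deletion by a median of 0.36 (0.49 and 0.75 within the shared days). A slower growth or another culture state of the deletion may explain it and cannot be told apart from loss of the gene: ribosome biogenesis moved by 0.143 (starvation; 0.0118 and 0.323 in its replicates) and 0.313 (cadmium) times the ribosomal protein median, which decides neither.

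The third pattern is that 4 of 10 sulfate uptake and reduction probes were higher in the starved wild type than in the starved deletion, and 0 lower. Scan day is argued against, since the 5 members at least 2-fold higher on the other day differed by a median of -3.73 within the shared day. The change of medium apart from the missing sulfur stays open, because starved and control cells differ in both. Of the 5 members called in the starved wild type, 2 were also called under cadmium, which may come from a demand for sulfur in both treatments or from something else they share. That these 4 depend on HpMET4 when sulfur is withheld is a hypothesis from the same data.

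Single arrays far from the other 3 of their group were found in 21 of 390 groups (5.39%), and chance flags about 1 in 20 groups. In the starved wild type these were INO1 on array 3 (6.27, others 6.12 to 6.14), ADH6 (-1.58), MET3 (1.42, others 2.49 to 2.61), MET2 (1.32, others 0.46 to 0.54), CPS1 (1.44) and BUL1 (0.54) on array 2, and MCM2 (1.40, others 0.91 to 0.99), MRPL51 (-0.91, others -0.16 to -0.14) and GRX4 (0.86, others 0.42 to 0.48) on array 1. In the starved deletion array 3 stood apart for PRB1 (5.01), PRC1 (2.96), HIS7 (0.999) and COX12 (-0.34), and array 4 for ARG8 (1.81), CAR2 (1.52), ARO8 (0.63) and SEO1 (0.63, others 0.01 to 0.09). In the wild type under cadmium array 2 stood apart for CAT (-1.82, others -0.93 to -0.76), SBA1 (0.34), RPS22A (0.29) and GCV3 (0.04), with the others of the last 3 negative.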

How the results depend on the processing

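Scan day as a fixed term on 15 arrays, lists without weakly similar probes and limma's treat were added after the result was seen; the other alternatives were planned. Counts follow in the order starved wild type, starved deletion, wild type under cadmium, deletion under cadmium, strain difference under starvation, strain difference under cadmium, starvation minus cadmium, and calls shared by both treatments in the wild type. As reported these were 750, 1747, 168, 2642, 701, 1697, 310 and 52. Apart from the block of replicate numbers, only counts that moved by over 1.5 times are given below, and where no reason is given the cause was not tested.

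With 15 arrays as replicates the starved wild type had 2201 calls, the starved deletion 2984, the wild type under cadmium 1329, the strain differences 1957 and 2740, starvation minus cadmium 1442 and the overlap 505. More units per group, which are not independent, go into that fit. With the dye-swap pair as a random block the counts were 1208 in the starved wild type, 466 in the wild type under cadmium, 1053 in the starvation difference, 602 in starvation minus cadmium and 146 shared. Without the single array, and equally without the pair of its group, they were in the same order 1339, 446, 1172, 577 and 147: either leaves that group no spread of its own. Scan day as a fixed term on 15 arrays gave 2477 and 3239 in the strain differences. Median pixels gave 111 in the wild type under cadmium, and median centring an overlap of 93. Scale normalization between arrays, which evens out response size by construction, gave 1512 (starved wild type), 1332 and 1525 (cadmium), 1030 (starvation minus cadmium) and 376 (overlap). With only the groups of a comparison in the fit these 5 were 1275, 1147, 1596, 821 and 303.

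Stricter thresholds lower counts by construction. At least 2-fold left 363, 811, 102 and 1270 in the 4 groups and 33 shared. An adjusted p under 0.01 left 287, 1033, 41, 1725, 268, 866, 91 and 16. Treat at 1.2-fold left 346 and 1085 under starvation, 61 in the wild type under cadmium, 438 and 177 in the starvation difference and starvation minus cadmium, and 19 shared. With the replicate number as a block, which stands for no known pairing, the counts were 733, 1723, 166, 2630, 708, 1665, 299 and 56. Camera with an estimated correlation passed 0 of 182 list tests, against 96 with the preset one and 88 by fry.

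Leaving out each array or pair in turn gave 193 to 1339, 840 to 2349, 5 to 446, 2277 to 2903, 267 to 1172, 599 to 2354, 41 to 577 and 1 to 147, and 86 to 97 lists. Without a pair, an arm of 1 replicate is assumed to vary like the other groups. Results that reversed were DDR48 in the cadmium difference (-1.35 with scale normalization), and ARO8 in the starved wild type (0.28) and MET2 in the starvation difference (-0.20) with the mean over a gene's probes, which point in opposite directions. Amino acid synthesis in the starved wild type reversed without its second pair, with camera adjusted p = 5.8e-06 to 0.903 over the arrays and pairs left out.

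Of 479 calls of named genes, all kept their direction and stayed past the threshold with 15 arrays as replicates, 430 with print-tip loess, 446 with scale normalization, 461 with median pixels, 455 with the mean over probes, 372 at an adjusted p under 0.01 and 368 to 472 without a pair. Of 96 list calls 71 held with fry, 84 without the single array, 85 without spots not found, 87 with median centring and 93 without weakly similar probes. Genes and lists that did not pass were not followed. The filter on spots marked bad removed none, so dropping it changes nothing. Spots marked not found were kept, and leaving them out gave 837 calls in the starved wild type. Scan day as a fixed term on the 8 replicates could not be fitted, and the deposited ratios were not run because 3 columns could not be matched. Signal over background limits the single array most (3937 probes above it, against 5358 or more on the others).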

Other observations

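The comparison of the control channels, its genes, the sulfur keyword probes with their bound, and the splits and exchanges that keep dye-swap pairs whole were chosen after the data were seen.

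Control RNA of the strains, grown in YPD per the labels, was compared across arrays as deletion minus wild type (4 replicates per strain). Limma called 8 of 5830 probes, 6 higher and 2 lower in the deletion, with 412 at an unadjusted p under 0.05. Higher were IME4 (4.20), MUM2 (3.28), KAR4 (2.77), YBR293W (2.60), KH-4899 (2.16) and SIT1 (2.12), and lower the METR probe KH-2783 (-3.57) and ECM13 (-2.70). Without the single array 4 stayed: IME4, MUM2, SIT1 and KH-2783. Of 35 splits of the 8 replicates 1, the real one, called as many (8 against 6 for the highest other). But 1 split was not fitted, and if it called as many the share would pass 0.05, so chance stays open. LEU2 differed by 1.93 (adjusted p = 0.403). By camera 6 of 26 lists differed: cytosolic ribosomal proteins (median 0.36; within the 2 shared scan days 0.49 and 0.75), histones (0.25; 0.43 and 0.22), amino acid synthesis (0.30; -0.06 and 0.30) and nitrogen (0.28; 0.04 and 0.02) were higher. Mitochondrial ribosomal proteins (-0.26; -0.01 and -0.07) and Met4 regulators (-0.36; -0.04 and -0.25) were lower. With an estimated correlation 0 lists passed.

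That sulfate genes are already lower in the deletion in the control medium was tested as a hypothesis. Their median difference in the control channels was 0.0376 (camera adjusted p = 0.65), within the spread of the members, so the question stays open.

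Probes named as sulfur genes of baker's yeast or other species, outside the fixed lists, were tested for following the sulfate list in the starved wild type. Of 12 such probes 4 rose, against 5 of 10 in the sulfate list. The probes were chosen after their values were seen, so the question stays open. The 4 were KH-1648, a cysteine synthase (1.18, adjusted p = 0.0111), KH-0569, a cystathionine beta-lyase (0.76, adjusted p = 0.0463), YHR112C, a cystathionine gamma-synthase (adjusted p = 0.00348), and KH-3361, an arylsulfatase (1.69, adjusted p = 0.00237). KH-3361 was lower in the starved deletion by a difference of -1.49 (adjusted p = 0.0224), and KH-0569 higher by 1.18 (adjusted p = 0.0332).

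For starvation minus cadmium in the wild type 3 splits keep the pairs whole, too few for a share under 0.05. The real one, 1 of them, called 1442 against 0 for the highest other. Exchanging treated and control RNA in whole pairs gives 2 arrangements, also too few. The real one, 1 in each case, called 2201 against 0 for the highest other in the starved wild type, 2984 against 0 in the starved deletion, 1329 against 0 in the wild type under cadmium and 3375 against 218 in the deletion under cadmium.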
